A study of Solanum lycopersicum with 24 samples.

How the data were processed

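RNA sequencing measured transcript abundance in leaves of tomato (Solanum lycopersicum, cultivar Fla. 8000). The 3 genotypes were wild type (WT) and the mutant lines Sldmr6-1.1 and Sldmr6-1.2. Leaves of 6-week-old plants kept at 25 °C with 16 h of light and 8 h of dark were infiltrated by syringe, either with a mock solution of 10 mM MgCl2 or with a suspension of the leaf-spot bacterium Xanthomonas gardneri (Xg) at an OD600 of 0.25, and collected 6 h later. Per the labels, 4 plants of each genotype and 2 leaves of each plant were used, which gave 6 groups of 4 libraries and 24 libraries in all. Groups and replicate numbers came from the sample titles.

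Per the labels' protocols, RNA was extracted with the Spectrum Plant Total RNA kit and libraries were made with the Illumina TruSeq stranded mRNA kit. The submitters' processing notes name bcl2fastq 2.20.0, Trim Galore 0.6.4, STAR 2.6.1c, featureCounts and Subread. Their settings, the genome build and the annotation are not given in the sources used here, nor is the treatment of strand or of reads that match several places, so values of near-identical or overlapping genes are uncertain. The deposited table holds whole-number counts of reads for 34075 tomato gene IDs in the 24 libraries, with no scaling, which was checked on its values. All 24 columns were matched to samples by the library codes in the labels. Library totals ranged from 4643222 to 5874122 counts, and 8417 IDs had no count in any library.

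The 36 pairs of libraries within a group were compared by a chi-square test of their counts. The chi-square per degree of freedom was 5.27 to 44.4, where 1 would be sampling noise, so no library was a repeat of another in its group. Pairs across groups were not compared. Counts were scaled with TMM factors and filtered with edgeR's filterByExpr at its minimum of 10 counts, which left 18140 IDs holding at least 99.7% of each library's counts. Comparisons used edgeR's quasi-likelihood F-test with robust shrinkage, 2-sided, in 1 fit of 6 groups over 24 libraries with no block. P-values were adjusted by the Benjamini-Hochberg method over the IDs tested, and an ID was called at an adjusted p under 0.05. Every adjusted p given for an ID is from this test unless another tool is named. The standard error (SE) of a log2 fold change is its size divided by the root of the F statistic. Levels are in CPM, from the cpm function of edgeR on the TMM-scaled totals, as mean ± SD of 4 libraries. Ratios against groups with 1 to 3 counts carry exact 95% intervals, which cover counting error only.

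The labels do not say which 2 libraries came from 1 plant. Deviations from the group mean were therefore correlated over genes. Same-numbered mock and Xg libraries of a genotype had r of 0.28 to 0.74 (mean 0.55, 12 pairs), and differently numbered ones −0.62 to 0.41 (mean −0.18). Deviations within a group sum to 0, which by itself pulls the latter mean below 0. Each of the 24 libraries matched its own number best, at times narrowly. WT-mock replicate 2 had r = 0.29 with its own number and 0.28 with WT-Xg replicate 4. Every pair lay above the limit of 0.1 set before the data were examined, so the numbers were taken to pair leaves within a genotype. A fit with each plant as a block is reported beside infection results that it changes. Between genotypes, same-numbered libraries had r of −0.54 to 0.58 (mean −0.02), and differently numbered ones −0.5 to 0.62 (mean 0.01). Some libraries of different genotypes therefore deviated together, without following the number.

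The gene table given for names (assembly SLM_r2.1, 41476 genes) matched 0 of the 34075 IDs, and the count table pairs no ID with a name. IDs are therefore printed as they stand, at most 2 that rose and 2 that fell in each comparison. The names SlDMR6-1 for Solyc03g080190 and SlDMR6-2 for Solyc06g073080 are those used in published work on tomato DMR6 and could not be checked against the table. IDs to be named were those with the largest fold change among calls that had every library of one group above every library of the other and at least 5 CPM in the higher group. For mutants against wild type both lines had to pass, and the smaller fold change was ranked. The planned requirement of an informative gene description could not be applied. For the difference of infection response no overlap condition was set, and IDs were taken from the fit with the plant as a block, a choice made after that fit's values were seen because the fit without it called none.

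Of 29 gene lists fixed before the data were examined, 18 were text patterns for gene descriptions and could not be used. These include every list of cell type markers, so a change in leaf cell makeup was not analysed here. The other 11 held 48 IDs recalled from published tomato work. Of these, 45 were in the table and 42 were tested. Their assignment to a list could not be checked here, and results are given by list. Lists with at least 3 tested IDs were tested with camera (preset correlation of 0.01, then an estimated one) and fry on log2 CPM, adjusted over lists and comparisons. The test in fry for change in either direction called no list (smallest adjusted p = 0.0678).

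Alternatives were DESeq2's size factors, DESeq2, limma voom, no filter on low counts, a filter of 1 CPM in 4 libraries, a fit of only the groups compared, a replicate block, and leaving out each library in turn. For comparisons that share control libraries, 20 sets of unchanged groups were simulated, wild-type libraries included, and the real controls were divided in 6 ways. Counts of calls were set against other splits of the same libraries. Tests were run on simulated counts for 18140 IDs, 100 of them changed 2-fold and 100 changed 4-fold. The test of infection in wild type recovered 52% and 79% of these with 4.38% false calls, that of Sldmr6-1.1 against wild type in mock leaves 47% and 81% with 2.29%, and that of the difference of response 23% and 59% without a block (0 false) and 54% and 83% with it (4.86%). In all simulated counts noise was drawn for each gene on its own, without shifts that many genes share. False calls may therefore be more frequent in the real libraries. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.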

Results

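Leaf transcripts were counted in wild-type tomato and in 2 lines mutant in SlDMR6-1, Sldmr6-1.1 and Sldmr6-1.2, 6 h after infiltration with mock solution or X. gardneri. DMR6 enzymes hydroxylate salicylic acid, a hormone of plant defence against pathogens. Each of the 6 groups held 4 libraries. Mean library totals were 4777156 ± 119294 counts in WT-mock, 4943658 ± 94894 in WT-Xg, 5056486 ± 132840 in Sldmr6-1.1-mock, 5647612 ± 275942 in Sldmr6-1.1-Xg, 5123599 ± 227624 in Sldmr6-1.2-mock and 5470539 ± 100719 in Sldmr6-1.2-Xg (SD, n = 4). The first principal component held 46.6% of the variance of log2 CPM and the second held 15.9%. Along the first, Xg libraries lay above mock libraries of the same genotype on average, and mutant libraries above wild-type libraries of the same treatment. Its mean score was −76.5 ± 14.1 in WT-mock, −18 ± 40 in Sldmr6-1.1-mock and −27.8 ± 19.1 in Sldmr6-1.2-mock, against −3.80 ± 21.2, 68.1 ± 41.6 and 58 ± 11.2 in the Xg groups of the same genotypes. Sldmr6-1.1 libraries spread most widely along it in both treatments.

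**Figure D1:**
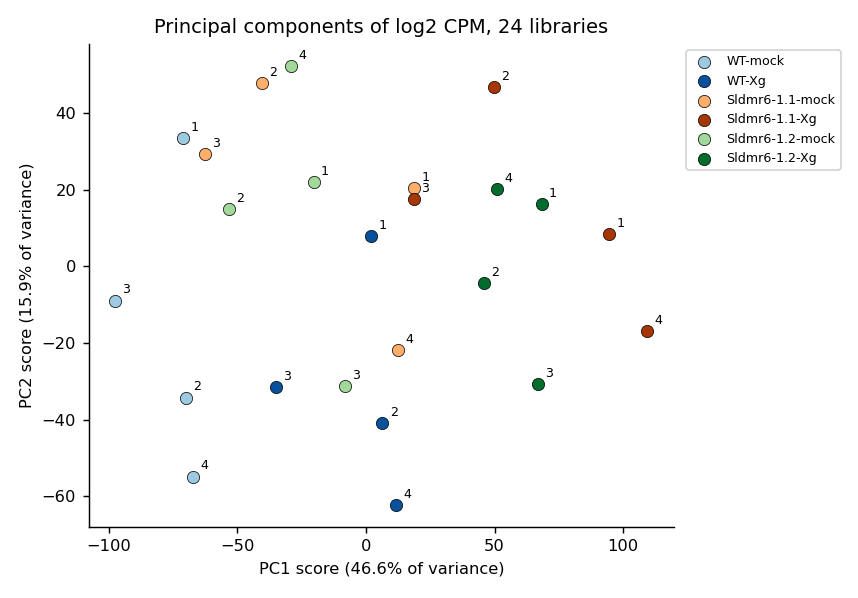
Scores of the 24 libraries on the first (x axis, 46.6% of variance) and second (y axis, 15.9%) principal components of log2 CPM, without units; colours give the group and digits the replicate number. Along the first component the mean of the WT-mock libraries is the lowest of the 6 groups and the means of the Xg libraries of both mutant lines are the highest.

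The targeted gene itself remained transcribed in both mutant lines. SlDMR6-1 (Solyc03g080190) stood at 197 ± 70.8 CPM in WT-mock leaves, 307 ± 72.7 in Sldmr6-1.1-mock and 500 ± 120 in Sldmr6-1.2-mock (SD, n = 4). It was 2.54-fold higher in Sldmr6-1.2 than in wild type in mock leaves (log2 1.35, SE 0.26, adjusted p = 0.003) and 1.93-fold higher in Xg leaves (593 ± 103 against 307 ± 106 CPM, log2 0.95, adjusted p = 0.0291). In Sldmr6-1.1 the log2 fold changes of 0.64 in mock leaves (adjusted p = 0.133) and 0.33 in Xg leaves (385 ± 66.2 CPM, adjusted p = 0.371) did not pass the test. Its paralog SlDMR6-2 (Solyc06g073080) was nearly silent in wild type, with 3 counts over the 4 WT-mock libraries, and reached 9.13 ± 4.20 CPM in Sldmr6-1.1-mock and 12.2 ± 10.2 CPM in Sldmr6-1.2-mock. The ratios to wild type were 62.0 (95% interval 20.9 to 303, adjusted p = 0.00107) and 82.9 (28.0 to 405, adjusted p = 0.000575). In Xg leaves SlDMR6-2 was at 0.341 ± 0.560 CPM in wild type, 4.38 ± 1.62 in Sldmr6-1.1 (log2 3.59, adjusted p = 0.00956) and 5.77 ± 4.86 in Sldmr6-1.2 (log2 3.98, adjusted p = 0.0129). These sizes rest on single libraries. WT-Xg replicate 4 held 6 of the 7 WT-Xg counts, and without it the log2 fold changes in Xg leaves were 5.62 and 6.02. Without Sldmr6-1.2-Xg replicate 4 that of Sldmr6-1.2 was 3.26 (adjusted p = 0.0515). In mock leaves the fitted log2 fold changes of 5.73 and 6.16 became 6.67 and 7.08 without WT-mock replicate 1, and that of Sldmr6-1.2 became 5.45 without its mock replicate 4.

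With infection SlDMR6-1 had a log2 fold change of 0.64 (SE 0.26) in wild type, which did not pass the test without a block (adjusted p = 0.128) and did with the plant as a block (0.65, adjusted p = 0.00103). In Sldmr6-1.1 the change was 0.32 without the block (adjusted p = 0.411) and 0.34 with it (adjusted p = 0.0384). In Sldmr6-1.2 it was 0.25 without the block (adjusted p = 0.533) and 0.26 with it (adjusted p = 0.102). SlDMR6-2 had log2 fold changes of −1.06 in Sldmr6-1.1 (adjusted p = 0.269) and −1.08 in Sldmr6-1.2 (adjusted p = 0.235), which did not pass without the block. With it they were −1.04 (adjusted p = 0.0394) and −1.05 (adjusted p = 0.0334). The labels do not describe the lesions, so a transcript level does not check which line a library came from. The call of SlDMR6-1 in Sldmr6-1.2-Xg was lost (adjusted p 0.0552 to 0.0925) when any one of WT-Xg replicates 2, 3 and 4 or Sldmr6-1.2-Xg replicates 1 and 4 was left out. Leaving out WT-mock replicate 1 made calls of its rise in wild-type infection (log2 0.90, adjusted p = 0.0354) and in Sldmr6-1.1-mock (log2 0.89, adjusted p = 0.0382). The calls of SlDMR6-2 in Xg leaves were lost with limma voom (adjusted p = 0.0662 and 0.0941).

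**Figure D2:**
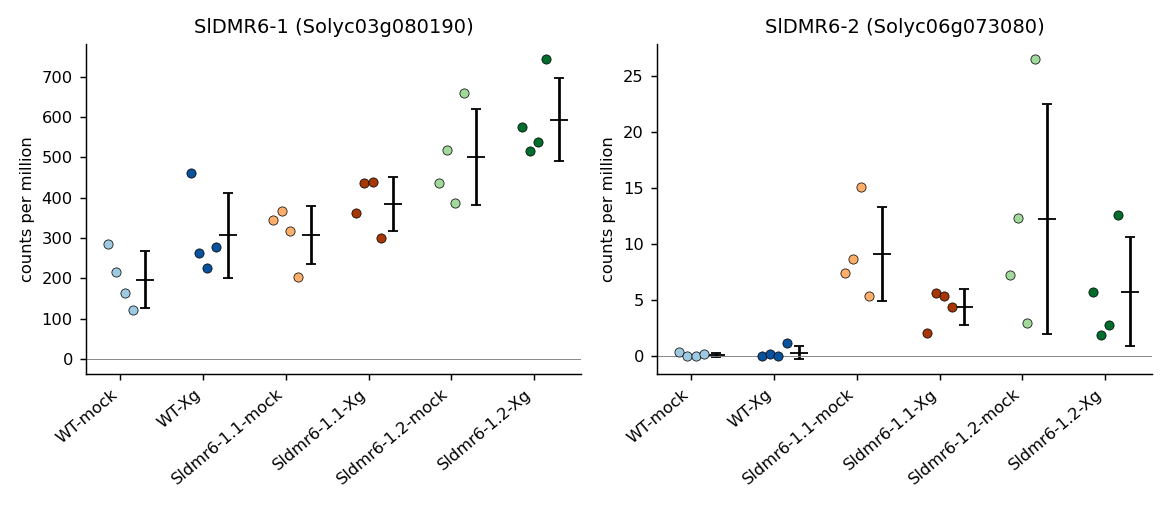
CPM (linear y axes) of SlDMR6-1 (left) and SlDMR6-2 (right) in each library of the 6 groups (x axis), with the mean and SD of 4 libraries as bars. SlDMR6-1 is highest in Sldmr6-1.2 (mean 593 CPM in Xg leaves), and SlDMR6-2 lies near 0 in wild type (mean 0.147 and 0.341 CPM) and above it in both mutant lines.

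The first question was how leaves of each genotype responded to the bacterium. In wild type, 1337 IDs rose and 280 fell, of which 754 and 50 changed at least 2-fold. Solyc10g006690 rose from 3 counts over the 4 WT-mock libraries to 6.78 ± 3.92 CPM, a ratio of 45.9 (95% interval 15.4 to 225, adjusted p = 0.000556). Solyc05g054820 rose from 0.644 ± 1.04 to 25.9 ± 9.86 CPM (log2 5.28, SE 1.10, adjusted p = 0.00358), and Solyc02g091920 fell from 23.3 ± 12.5 to 6.05 ± 3.05 CPM (log2 −1.94, SE 0.51, adjusted p = 0.0183). Solyc07g032490 fell from 11.3 ± 6.57 to 2.34 ± 1.47 CPM (log2 −2.26, SE 0.66, adjusted p = 0.0333). WT-mock replicate 2 held 11 of the 13 WT-mock counts of Solyc05g054820, and without it the log2 fold change was 7.40 for this ID and 6.26 for Solyc10g006690 (fitted 5.31 with it).

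Sldmr6-1.1 had 3701 calls (2060 higher, 1641 lower) and Sldmr6-1.2 had 3859 (1970 higher, 1889 lower). All 3 genotypes shared 1033 IDs that rose and 206 that fell. Wild type shared 1077 higher and 218 lower IDs with Sldmr6-1.1, where independent lists would share 151.8 and 25.3, and 1148 and 238 with Sldmr6-1.2 (145.2 and 29.2). In neither pair was an ID called in opposite directions without the block, and with it 8 were, between wild type and Sldmr6-1.1. With the plant as a block the calls were 5399 in wild type (2968 higher, 2431 lower), 7165 in Sldmr6-1.1 (3505 higher, 3660 lower) and 7427 in Sldmr6-1.2 (3466 higher, 3961 lower), and the 3 genotypes shared 2190 higher and 1901 lower IDs. Larger counts in the mutants do not by themselves show a larger response, and the difference was tested separately.

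**Figure D3:**
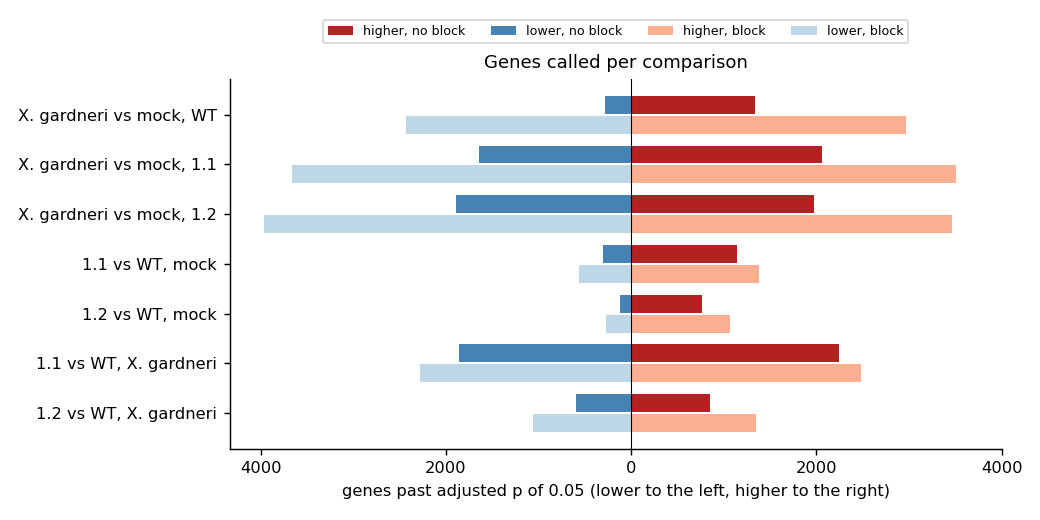
Number of IDs at an adjusted p under 0.05 (x axis, lower to the left and higher to the right of 0) in 7 comparisons (y axis), without a block (dark bars) and with one (pale bars; the plant for infection, the replicate number for mutants against wild type). Infection in wild type gave 1337 higher and 280 lower IDs without the block, and 2968 and 2431 with it.

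Several defence lists moved with infection. All 4 tested IDs of the receptor kinase list, cell-surface sensors of microbes, rose in each genotype, by log2 up to 3.50 in wild type, 3.14 in Sldmr6-1.1 and 3.19 in Sldmr6-1.2, and the same 4 passed when adjusted over the list alone. As a list they stood above the other genes (camera adjusted p = 7.37e-05, 0.000207 and 0.000286), but not with an estimated correlation (adjusted p = 0.0841 in each). Of the 12 salicylic acid IDs, 4 rose in wild type (5 adjusted over the list alone) and 5 in each mutant line (also 5 over the list alone, with 1 lower in Sldmr6-1.2), and none fell over all genes. The camera adjusted p was 0.00748 in wild type, 0.0988 in Sldmr6-1.1 and 0.0407 in Sldmr6-1.2, and with an estimated correlation the adjusted p = 0.381, 0.669 and 0.561. Of 4 ethylene IDs, from the synthesis and response of that hormone, 2 rose in each genotype, also adjusted over the list alone. Their camera adjusted p was 0.00748, 0.0104 and 0.0682, against an adjusted p of 0.234, 0.280 and 0.324 with an estimated correlation. Of 9 jasmonate IDs, from the wound hormone pathway, 1 rose in wild type, 3 in Sldmr6-1.1 and 1 in Sldmr6-1.2, the same numbers as adjusted over the list alone, and the list did not stand apart (camera adjusted p = 0.983, 0.553 and 0.625). None of 3 wound defence IDs passed in any genotype without the block (camera adjusted p = 0.519, 0.792 and 0.874), while the plant block called 2 lower in wild type, 1 higher and 1 lower in Sldmr6-1.1 and 1 lower in Sldmr6-1.2. By fry, which tests whether the IDs of a list move on balance in one direction and does not compare them with other genes, the receptor kinases (adjusted p = 3.4e-05 in each genotype) and the ethylene list (0.00249, 0.00249 and 0.0102) moved upward. The salicylic acid list passed fry in wild type (adjusted p = 0.0262) but not in Sldmr6-1.1 (0.122) or Sldmr6-1.2 (0.0584), and with the plant block it passed in all 3 (0.000109, 0.000274 and 0.000109).

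Lists with fewer than 3 tested IDs were counted only. Of 2 TAL targets, plant genes switched on by the injected activator proteins of Xanthomonas, 1 rose in every genotype, by log2 3.74 in wild type, 3.51 in Sldmr6-1.1 and 3.74 in Sldmr6-1.2. The single signalling ID of the list of kinases and respiratory burst oxidases rose by log2 1.40, 1.95 and 1.73 in the same order. Of 2 phenylpropanoid IDs, from the pathway of lignin and phenolics, 1 rose in wild type and 2 in each mutant line, and adjusted over the list alone 2 rose in all 3 genotypes. Of 2 pathogenesis-related (PR) protein IDs, 1 rose in wild type and none in the mutants, and the single abscisic acid ID passed nowhere over all genes without the block. These counts were the same adjusted over the list alone for the TAL, signalling and PR lists, while the abscisic acid ID fell in Sldmr6-1.2 (log2 −1.09). With the plant as a block, salicylic acid IDs numbered 6, 6 and 7 higher and 1 lower in each genotype. The block also called 1 jasmonate ID lower in wild type, 4 in Sldmr6-1.1 and 3 in Sldmr6-1.2, where 2 jasmonate IDs were higher in place of 1. It called both phenylpropanoid IDs higher in wild type, the abscisic acid ID lower in Sldmr6-1.2, and in each mutant line 1 PR protein ID higher and 1 TAL target lower.

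Among the named IDs, the fall of Solyc07g032490 was lost (adjusted p 0.0515 to 0.110) without any one of WT-mock replicates 1, 2 and 3 or WT-Xg replicates 1, 2 and 4 and with limma voom, that of Solyc02g091920 (0.0653 to 0.0762) without WT-mock replicate 1 or WT-Xg replicates 2 or 4, and the rise of Solyc05g054820 with limma voom (adjusted p = 0.128), while the block kept both falls (adjusted p = 0.00119 and 5.52e-06). Counts of calls fell to 973 and 1074 in wild type without WT-mock replicate 3 or WT-Xg replicate 2, to 2286, 2455 and 1990 in Sldmr6-1.1 without its mock replicate 3 or Xg replicates 1 or 4, and to 2280 in Sldmr6-1.2 without its mock replicate 2. A fit of only the 8 Sldmr6-1.1 libraries gave 1257.

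The second question was how mock leaves of the mutant lines differed from those of wild type. If the leaves were paired as taken from the replicate numbers, the other leaf of each plant was given X. gardneri. An effect of that leaf on the mock leaf cannot be told apart from one of the mutation. Sldmr6-1.1-mock leaves differed from WT-mock at 1449 IDs (1146 higher, 303 lower) and Sldmr6-1.2-mock leaves at 884 (761 higher, 123 lower). Solyc10g084960 rose from 0.743 ± 0.696 CPM in wild type to 100 ± 36.3 in Sldmr6-1.1 (log2 7.04, SE 0.51, adjusted p = 2.42e-08) and 109 ± 21.4 in Sldmr6-1.2 (log2 7.16, SE 0.51, adjusted p = 1.82e-08). Solyc01g066790 had 1 count in all of WT-mock and stood at 14.3 ± 7.93 and 9.29 ± 3.65 CPM in the lines, ratios of 288 (95% interval 51.3 to 11400, adjusted p = 4.43e-06) and 189 (33.5 to 7490, adjusted p = 2.1e-05). Solyc09g008320 fell from 12.2 ± 3.03 CPM to 1.36 ± 1.69 (log2 −3.13, adjusted p = 0.00234) and 1.23 ± 0.656 (log2 −3.28, adjusted p = 0.00221). Solyc10g079320 fell from 6.26 ± 3.10 CPM to 0.882 ± 0.340 (log2 −2.79, adjusted p = 0.00303) and 1.23 ± 0.590 (log2 −2.32, adjusted p = 0.011). Without WT-mock replicate 4 the log2 fold changes of Solyc10g084960 were 7.70 and 7.82, and without Sldmr6-1.1-mock replicate 3, which held 20 of the 28 counts of its group, that of Solyc09g008320 in Sldmr6-1.1 was −4.50. The single WT-mock count of Solyc01g066790 was in replicate 1, and without it wild type is at 0.

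Both PR protein IDs, antimicrobial proteins that mark salicylic acid signalling, were higher in Sldmr6-1.1-mock and 1 in Sldmr6-1.2-mock, or 2 in each line adjusted over the list alone, with log2 fold changes of 2.93 and 5.80 in Sldmr6-1.1 and 2.92 and 3.36 in Sldmr6-1.2. Of 12 salicylic acid IDs, 6 were higher and 1 lower in Sldmr6-1.1 (7 and 1 adjusted over the list alone) and 3 were higher in Sldmr6-1.2 (7 over the list alone). The camera adjusted p was 0.00495 and 0.000506, and with an estimated correlation the adjusted p = 0.355 and 0.307. Of 4 ethylene IDs 2 were higher in each line, also over the list alone (camera adjusted p = 0.00495 and 0.00748, and adjusted p = 0.231 and 0.234 with an estimated correlation). Of 4 receptor kinase IDs 1 was higher and 1 lower in each line, or 2 higher and 1 lower in Sldmr6-1.1 over the list alone, and the list did not stand apart (camera adjusted p = 0.983 and 0.756). No jasmonate ID passed over all genes, and 1 was higher in Sldmr6-1.2 over the list alone (camera adjusted p = 0.553 and 0.935). None of the wound defence (camera adjusted p = 0.772 and 0.581), TAL target, signalling, phenylpropanoid and abscisic acid IDs passed in either line, nor adjusted over those lists alone. By fry the salicylic acid list (adjusted p = 0.0272 and 0.0115) and the ethylene list (0.00249 and 0.00424) moved upward in both lines, and no other list passed.

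In mock leaves both lines shared 639 higher and 60 lower IDs, where independent lists would share 48.1 and 2.10, and 1 ID went opposite ways. In 20 simulations without a change, which drew the wild-type libraries anew, the lines shared 0 calls. Each gene was drawn on its own, so a shift of many genes together in the real WT-mock libraries is not excluded. The fold changes of the lines correlated across genes, which are not independent replicates, at r = 0.83 against 0.50 in the simulations, with a covariance of 0.375 against 0.0714. With the wild-type libraries divided between the lines, 183 to 246 calls were shared and r was 0.48 to 0.66. The mean covariance was then 0.321. Each line had fewer controls in these fits, which by itself lowers the number of calls. Counts fell in Sldmr6-1.1 to 882, 945, 960, 680 and 904 without WT-mock replicates 2, 3 or 4 or its mock replicates 1 or 4, in Sldmr6-1.2 to 555, 541 and 589 without WT-mock replicate 2 or its mock replicates 1 or 4, and for the shared calls from 699 to 456 without WT-mock replicate 2. A fit of only the groups compared gave 342 calls in Sldmr6-1.1, 559 in Sldmr6-1.2 and 264 shared.

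The same contrast was drawn in infected leaves. Sldmr6-1.1-Xg leaves differed from WT-Xg at 4103 IDs (2243 higher, 1860 lower) and Sldmr6-1.2-Xg leaves at 1448 (852 higher, 596 lower). Solyc01g066790 again rose, from 3 counts over WT-Xg to 32.3 ± 11.8 and 21.3 ± 5.97 CPM, ratios of 221 (95% interval 75.1 to 1070, adjusted p = 7.9e-07) and 146 (49.7 to 711, adjusted p = 4.41e-06). Solyc03g093930 rose from 0.341 ± 0.460 CPM to 46.9 ± 26.6 (log2 7, adjusted p = 6.88e-05) and 23.8 ± 6.64 (log2 6.02, adjusted p = 0.000658). Solyc09g008320 fell from 6.15 ± 0.726 CPM to 0.620 ± 0.328 (log2 −3.26, adjusted p = 0.00251) and 0.565 ± 0.664 (log2 −3.38, adjusted p = 0.00552). Solyc01g109500 fell from 19.4 ± 9.63 CPM to 0.955 ± 0.628 (log2 −4.32, adjusted p = 0.00752) and 2.03 ± 1.71 (log2 −3.24, adjusted p = 0.0416). Without WT-Xg replicate 3 the fitted log2 fold changes of Solyc01g066790 went from 7.56 and 6.97 to 8.52 and 7.93, and without WT-Xg replicate 4 those of Solyc03g093930 were 8.25 and 7.27. Without Sldmr6-1.2-Xg replicate 3 the falls in Sldmr6-1.2 were log2 −4.47 for Solyc09g008320 and −3.90 for Solyc01g109500.

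Both PR protein IDs were higher in both lines in infected leaves, also adjusted over the list alone, by log2 2.12 and 5.58 in Sldmr6-1.1 and 1.80 and 4.04 in Sldmr6-1.2. Of 12 salicylic acid IDs, 4 were higher and 1 lower in Sldmr6-1.1, the same numbers over the list alone, and 3 were higher in Sldmr6-1.2 (5 over the list alone). The camera adjusted p was 0.0928 and 0.0031, and with an estimated correlation the adjusted p = 0.669 and 0.324. Of 4 ethylene IDs 3 were higher in Sldmr6-1.1 and 2 in Sldmr6-1.2, also over the list alone (camera adjusted p = 0.0179 and 0.0682, and adjusted p = 0.307 and 0.324 with an estimated correlation). Of 9 jasmonate IDs 3 were higher in Sldmr6-1.1 and 1 in Sldmr6-1.2, or 3 and 2 over the list alone (camera adjusted p = 0.148 and 0.438). Of 4 receptor kinase IDs 2 were higher and 1 lower in Sldmr6-1.1 and 1 was higher and 1 lower in Sldmr6-1.2, or 2 and 1 in each over the list alone (camera adjusted p = 0.861 and 0.656). The signalling ID was higher in Sldmr6-1.1 (log2 0.91) and 1 of 2 phenylpropanoid IDs in the same line, while over the list alone 1 phenylpropanoid ID also passed in Sldmr6-1.2. No wound defence (camera adjusted p = 0.999 and 0.983), TAL target or abscisic acid ID passed in either line, nor adjusted over those lists alone. By fry the ethylene list moved upward in both lines (adjusted p = 0.00305 and 0.0321), the jasmonate list in Sldmr6-1.1 (0.00424, against 0.134 in Sldmr6-1.2) and the salicylic acid list in Sldmr6-1.2 (0.0289, against 0.125 in Sldmr6-1.1).

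In infected leaves the lines shared 785 higher and 477 lower IDs, where independent lists would share 105.3 and 61.1, and 2 IDs went opposite ways. Unchanged groups simulated in the same way, with the same limit, shared 0 calls. Across genes the correlation was 0.86 against 0.51 simulated and the covariance 0.434 against 0.0689. With the wild-type libraries divided, and so fewer controls for each line, the lines shared 75 to 311 calls. There r was 0.59 to 0.71 and the mean covariance was 0.384. Across both treatments 425 IDs were higher and 43 lower in both lines. The fall of Solyc01g109500 was lost with limma voom (adjusted p = 0.103 in Sldmr6-1.1 and 0.150 in Sldmr6-1.2), and in Sldmr6-1.2 also without a filter (0.066) and without any one of WT-Xg replicates 2, 3 and 4 or its Xg replicates 1, 2 and 4 (adjusted p 0.0719 to 0.129). The rise of Solyc03g093930 in Sldmr6-1.2 was lost with limma voom (0.0948). Counts fell in Sldmr6-1.1 to 2610, 2396 and 2245 without WT-Xg replicate 3 or its Xg replicates 1 or 4, in Sldmr6-1.2 to 628, 484, 836, 519 and 587 without WT-Xg replicates 2, 3 or 4 or its Xg replicates 1 or 4, and for the shared calls from 1262 to 563, 436, 729, 478 and 550 without the same 5 libraries. A fit of only the groups compared gave 2159 and 2371.

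Whether the infection response itself differed between genotypes was tested as the difference of the 2 log2 fold changes. Solyc04g007380 rose with infection from 0.743 ± 0.617 to 14.2 ± 5.25 CPM in wild type, while it already stood at 33.5 ± 13.6 CPM in Sldmr6-1.1-mock and 35.3 ± 9.15 in Sldmr6-1.2-mock and reached 68.1 ± 19.4 and 65.5 ± 9.04 in the Xg leaves of these lines. Its response differed from that of wild type by log2 −3.17 (SE 0.32, adjusted p = 0.000108) in Sldmr6-1.1 and −3.32 (SE 0.31, adjusted p = 8.03e-05) in Sldmr6-1.2 with the plant as a block. Solyc07g056210 went from 6.49 ± 4.44 to 29.3 ± 8.46 CPM in wild type, 157 ± 63.0 to 220 ± 40 in Sldmr6-1.1 and 140 ± 19.6 to 208 ± 29.0 in Sldmr6-1.2, a difference of log2 −1.68 (SE 0.23, adjusted p = 0.00639) and −1.65 (SE 0.23, adjusted p = 0.0118). With the block, the response differed at 29 IDs in Sldmr6-1.1 (7 higher, 22 lower) and 11 in Sldmr6-1.2 (all lower), of which 7 lower ones were shared. Of the lower ones, 18 of 22 in Sldmr6-1.1 and 10 of 11 in Sldmr6-1.2 were called higher than wild type in mock leaves. The same mock libraries enter both tests, and a high mutant or low wild-type mock level by itself lowers the difference of response. The calculation therefore favours this overlap, its size under noise alone was not tested, and no conclusion is drawn from it. A lower response here is a smaller fold change, while both named IDs gained more CPM in the mutants than in wild type. No ID of any list passed in either line over all genes, with or without the block, and adjusted over the list alone 1 jasmonate ID had a larger response in Sldmr6-1.1. No list passed camera or fry for these differences.

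Without the block edgeR called 0 IDs in either line, with 528 and 395 at an unadjusted p under 0.05, and DESeq2 called 1 in each, Solyc04g007380 (adjusted p = 0.000593 and 0.000147). The edgeR differences without the block were log2 −3.20 (adjusted p = 0.262) and −3.33 (adjusted p = 0.150) for Solyc04g007380, and −1.69 and −1.60 (adjusted p = 1 in both) for Solyc07g056210. They became −3.86 and −3.99 for Solyc04g007380 without WT-mock replicate 4, and −2.28 and −2.19 for Solyc07g056210 without WT-mock replicate 1. Both lines are set against the same wild-type response. Unchanged groups simulated gene by gene, with the same limit, shared 0 IDs. They gave r = 0.52 across genes against the observed 0.60, with a covariance of 0.0627 against 0.0966. With the wild-type plants divided, 2 to 4 IDs were shared, r was 0.08 to 0.21 and the mean covariance was 0.0347.

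**Figure D4:**
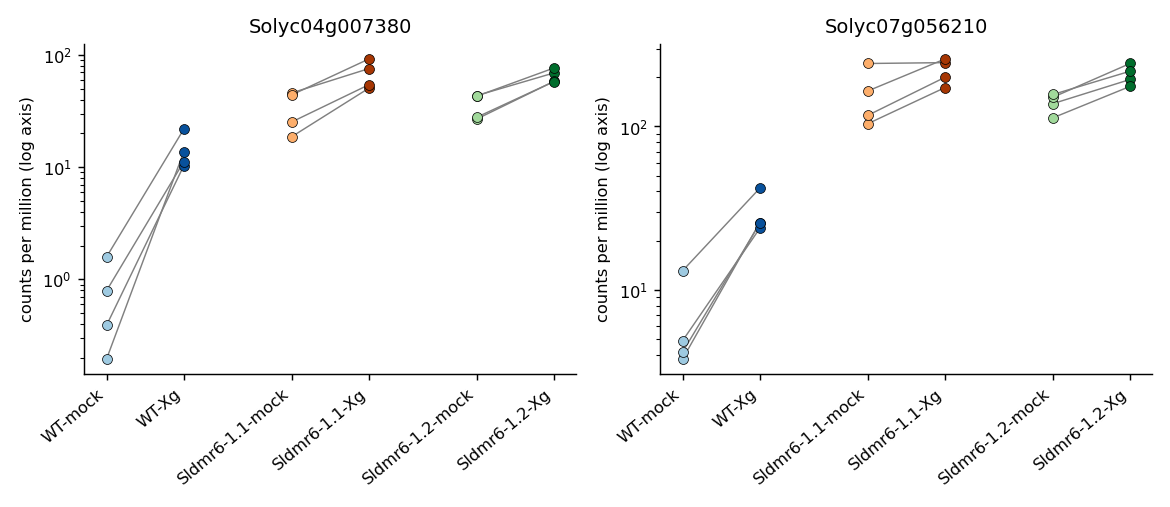
CPM (log y axes) of Solyc04g007380 (left) and Solyc07g056210 (right) in each library (points) of the 6 groups (x axis), with lines joining the mock and Xg libraries of the same replicate number. In wild type the group means rise from 0.743 to 14.2 CPM and from 6.49 to 29.3 CPM, and in both mutant lines the group mean of mock leaves lies above that of infected wild-type leaves.

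The lines were also compared with each other. As the lesions are not described, an effect of different alleles of the shared gene cannot be told apart from a difference elsewhere. The lines differed at 7 IDs in mock leaves (3 higher in Sldmr6-1.1, 4 lower) and 14 in Xg leaves (9 higher, 5 lower). Solyc04g049450 stood at 170 ± 25.7 CPM in Sldmr6-1.1-mock and 135 ± 45.4 in WT-mock but had 2 counts over the 4 Sldmr6-1.2-mock libraries, a ratio between the lines of 1720 (95% interval 476 to 14200, adjusted p = 7.61e-13). In Xg leaves it was at 279 ± 32.8 CPM in Sldmr6-1.1, 303 ± 79.5 in wild type and 0.190 ± 0.00229 in Sldmr6-1.2 (log2 10.35 between the lines, SE 0.39, adjusted p = 2.2e-13). Solyc01g081250 was also higher in Sldmr6-1.1, at 25.3 ± 6.45 and 48.5 ± 14.9 CPM in Sldmr6-1.1-mock and Sldmr6-1.1-Xg, with 3 counts in each Sldmr6-1.2 group, ratios of 172 (58.5 to 836, adjusted p = 4e-08) and 339 (116 to 1650, adjusted p = 2.4e-09), but had only 1 and 2 counts in the wild-type groups. Solyc07g007770 was at 5.47 ± 1.60 and 5.03 ± 1.57 CPM in the mock and Xg leaves of Sldmr6-1.2, against 2 and 1 counts in Sldmr6-1.1, ratios of 55.8 (15.1 to 466, adjusted p = 0.000811) and 106 (18.6 to 4230, adjusted p = 0.000516). Solyc01g105450 was at 29.9 ± 13.4 CPM in Sldmr6-1.1-Xg and 122 ± 38.5 in Sldmr6-1.2-Xg (log2 −2.02, SE 0.31, adjusted p = 0.00492). The fitted log2 fold changes of Solyc01g081250 went from 7.21 to 8.14 without Sldmr6-1.2-mock replicate 1 and from 8.18 to 9.11 without Sldmr6-1.2-Xg replicate 4. The single Sldmr6-1.1-Xg count of Solyc07g007770 was in replicate 2, and without it that group is at 0.

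No listed ID differed between the lines over all genes, while adjusted over the list alone 1 PR protein ID was higher in Sldmr6-1.1-mock, 1 jasmonate and 1 ethylene ID higher in Sldmr6-1.1-Xg, and 1 DMR6 family ID lower in Sldmr6-1.1 in both treatments. The infection response of the lines differed at 0 IDs without the block (231 at an unadjusted p under 0.05, and 0 with DESeq2) and at 1 with it, Solyc09g008430 (log2 0.81, SE 0.11, adjusted p = 0.0286), named because it was the only one. The call of Solyc01g105450 was lost in a fit of only the groups compared (adjusted p = 0.294), which called 4 IDs in each treatment, and DESeq2 called 15 and 39. Leaving out Sldmr6-1.1-Xg replicates 1, 3 or 4 or Sldmr6-1.2-Xg replicates 1, 2 or 4 gave 8, 29, 8, 9, 8 and 9 calls in Xg leaves.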

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

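The tests of a mislabelled library, of a near-identical copy, of thinned counts with the plant block and along the axis, and of random gene sets, below, were chosen after the results were seen. Of 114 groups of 4 values examined, 10 held 1 value far from the others by Dixon's test, where chance gives about 5.70. Of these, 4 rest on about 1 count: Solyc01g066790 in WT-mock replicate 1 (0.196 CPM, others 0), Solyc01g081250 in WT-mock replicate 4 (0.199 CPM, others 0), Solyc07g007770 in Sldmr6-1.1-Xg replicate 2 (0.188 CPM, others 0) and Solyc04g049450 in Sldmr6-1.2-Xg replicate 3 (0.187 CPM, others 0.191 to 0.192). SlDMR6-2 (Solyc06g073080) stood at 1.17 CPM in WT-Xg replicate 4 and at 0 to 0.196 in the other 3. Solyc07g056210 stood at 13.1 CPM in WT-mock replicate 1 (others 3.78 to 4.89) and at 41.9 CPM in WT-Xg replicate 1 (others 23.8 to 25.8). Solyc09g008320 stood at 3.87 CPM in Sldmr6-1.1-mock replicate 3 (others 0.196 to 0.786) and Solyc01g109500 at 14.0 CPM in Sldmr6-1.2-mock replicate 3 (others 1.96 to 3.37). The total of WT-Xg replicate 1 was 5084594 counts, against 4877997 to 4907897 in the other 3.

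A difference between genotypes in the response to infection was called at 29 IDs in Sldmr6-1.1, 11 in Sldmr6-1.2 and 1 between the lines, each with the plant as a block. The difference from wild type was log2 −3.17 in Sldmr6-1.1 and −3.32 in Sldmr6-1.2 for Solyc04g007380, and −1.68 and −1.65 for Solyc07g056210. Only the real split of 35 gave as many as 29 calls in Sldmr6-1.1, with 18 as the highest other. That share is the smallest that 35 splits allow and was not adjusted over the counts tested. Chance is therefore less likely for that count but is not excluded. For Sldmr6-1.2, 2 of 35 splits gave as many as 11, with 113 as the highest other, and between the lines 4 of 35 gave as many as 1, with 59 as the highest other, so chance cannot be excluded for either count. Splits that call several times the real number point to a structure of the samples, and what it is was not tested.

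The first pattern weighed is the pair of line-specific IDs: Solyc04g049450 was almost absent from Sldmr6-1.2 and Solyc01g081250 was almost absent outside Sldmr6-1.1. A mislabelled library is argued against, because 0 of 24 libraries lay nearer to another genotype than to their own over 20 IDs chosen on the other plants alone. Loss of a stretch of chromosome holding several genes is argued against for Solyc04g049450. Its 10 nearest tested IDs by number had a median log2 difference (Sldmr6-1.2 minus Sldmr6-1.1) of −0.04 in mock leaves, from −0.37 to 0.20, with 0 called. A loss limited to this gene was not tested. Reads moved to a near-identical copy cannot be told apart from a loss of the transcript. The 4 IDs called higher in Sldmr6-1.2 gained 9.47% of the CPM that Solyc04g049450 lost. A gain of an abundant ID need not be called, 20 of 34075 IDs, called or not, each gained at least 50% of the loss in both treatments, and the treatment of reads that match several places is not given in the sources used here. A heritable difference between the lines at these genes may remain, as a hypothesis that the design does not test.

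The second pattern is the larger number of infection calls in the mutants, 3701 and 3859 against 1617. With the plant as a block the excess was smaller (7165 and 7427 against 5399), and a fit of only the groups compared gave 1257 in Sldmr6-1.1, 4022 in Sldmr6-1.2 and 1349 in wild type, so the excess in Sldmr6-1.1 depends on the fit. Library size is argued against for the counts without the block, because with every library thinned to 4643222 counts the mutant line with fewer calls still had 2.25 times as many as wild type (mean of 5 draws, 2.21 to 2.35). With the plant block this ratio was 1.33 before thinning and 1.31 after it (1.28 to 1.32). A larger response per plant was tested on genes called with the block in the other mutant line, as the mean signed log2 change between the leaves of a plant. In Sldmr6-1.2 it was 0.78 ± 0.08 against 0.62 ± 0.07 in wild type (SD, n = 4, 7165 genes, higher in 4 of 4 plants than in any wild-type plant, exact 2-sided permutation p = 0.0286, the smallest these plants allow, adjusted 0.114 over 4 tests), and in Sldmr6-1.1 it was 0.75 ± 0.08 against 0.63 ± 0.07 (7427 genes, 3 of 4 plants above all wild-type plants, exact permutation p = 0.0571, adjusted 0.114). Neither passed after the adjustment. A larger response is consistent with the values of Sldmr6-1.2 before it, cannot be told apart from the spread between 4 plants in Sldmr6-1.1, and may be overstated in both, since the genes were chosen in a mutant.

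The third pattern is the difference between plants of 1 genotype: a single axis held 35.8% of the variance within groups, and leaves of the same number deviate together, which is how they were taken as pairs. Unequal depth at counting is argued against as its source. With every library thinned to 4643222 counts the main axis still held 35.4% (mean of 5 draws, 35.3% to 35.5%). Log2 CPM were already scaled to the totals, so thinning bears on counting noise alone. Over the 24 libraries the axis and the library total had r = −0.04 (permutation p = 0.882). Within groups r ran from −0.86 in WT-mock to 0.91 in Sldmr6-1.1-Xg. A cause that acts on both before counting therefore stays open. The weights of genes on the axis correlated at 0.53 with the wild-type infection log2 fold changes, across genes, which are not independent replicates. Over the 8 mutant plants, deviations along the wild-type infection response in mock and Xg leaves had r = 0.92 (exact permutation p = 0.0104, adjusted 0.0156 over 3 relations, r = 0.91 without the 2 farthest) and rho 0.98 (exact permutation p = 0.0208). Leaves of a plant deviate together over all genes, so the same r was computed for 1000 random sets of 1617 IDs matched on spread, of which 1 was as high (median r 0.44). The IDs of random sets do not move together, so a set moved together by another cause is not excluded. A candidate explanation is that plants differed in their position along the infection response, while growth position, handling and day were not tested.

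For infection, the highest other of 35 splits gave 454 calls in wild type (real 1617), 3350 in Sldmr6-1.1 (real 3701) and 1 in Sldmr6-1.2 (real 3859). Leaves were taken as paired by plant, and only 8 splits part all 4 pairs as the real one does, too few for a share under 0.05. The highest other of these 8 was 0 in each genotype. The counts of 454 and 3350 came from splits that part 2 pairs, and splits that part none gave up to 3, 1271 and 1. For the other counts of calls, the share was under 0.05 where only the real split gave as many, without adjustment over the counts tested. That held for mock leaves of Sldmr6-1.1 (1449, highest other 36) and Sldmr6-1.2 (884, highest other 370), and for Xg leaves of these lines (4103 with 1590 and 1448 with 0). It held for calls shared by both lines in mock leaves (699, highest other of 100 splits 45) and Xg leaves (1262, highest other 1), and between the lines in Xg leaves (14, highest other of 35 splits 0). Between the lines in mock leaves 2 of 35 splits gave as many as 7, with 73 as the highest other, so chance cannot be excluded, and 73 points to a structure of the samples.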

How the results depend on the processing

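All alternatives were chosen before the data were examined. Where a value moved, the cause was not tested. DESeq2's size factors and both other filters left every count within 1.5 times its value, and so did limma voom. DESeq2 gave 1 call for the difference of response in each line in place of 0, and 15 and 39 calls between the lines in place of 7 and 14 (mock and Xg). A fit of only the groups compared gave 1257 calls for infection in Sldmr6-1.1, 342 and 559 for Sldmr6-1.1 and Sldmr6-1.2 in mock leaves with 264 shared, 2159 and 2371 in Xg leaves, and 4 between the lines in each treatment.

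With the plant as a replicate block, infection gave 7427 calls in Sldmr6-1.2, 7165 in Sldmr6-1.1 and 5399 in wild type, and the difference of response 29, 11 and 1 (the last between the lines). The block removed variation between plants, and the common biological variation fell from 26% to 11.1%. Across genotypes the libraries share only a number, and a replicate block on that number gave 1337 calls for Sldmr6-1.2 in mock leaves, 2416 in Xg leaves and 2102 shared in Xg leaves, and left the other counts within 1.5 times. The blocks changed no call of a camera test, and in fry the plant block added calls of the salicylic acid list for infection in Sldmr6-1.1 and Sldmr6-1.2, with no other call of fry changed by either block. Directions that turned were all uncalled: jasmonate in the difference of response between the lines (plant block, camera adjusted p = 0.930), wound defence with the replicate number as a block in Sldmr6-1.1-Xg (0.907) and between the lines in Xg leaves (0.913), and SlDMR6-2 in wild-type infection without WT-Xg replicate 4 (log2 −0.94, adjusted p = 0.859, against up to 2.03 without another library).

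Leaving out 1 library at a time gave 973 to 2171 calls for infection in wild type, 1990 to 4951 in Sldmr6-1.1 and 2280 to 3945 in Sldmr6-1.2. For the lines against wild type it gave 680 to 1752 (Sldmr6-1.1) and 541 to 988 (Sldmr6-1.2) in mock leaves with 456 to 796 shared, and 2245 to 5329 and 484 to 1461 in Xg leaves with 436 to 1639 shared. Between the lines it gave 5 to 6 in mock and 8 to 29 in Xg leaves, and for each difference of response 0 without the block. The fit with the plant block was not repeated in this way. Of 704 values of single IDs under the alternatives, 661 kept their direction and side of the threshold, 30 lost a call, 12 gained one and 1 reversed. All 13 calls of camera tests were lost with an estimated correlation, and 47 list results held. At 4643222 to 5874122 counts per library an ID with 1 to 3 counts in a group has a ratio known only within wide limits.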

Other observations

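The tests in this part were chosen after the results were seen. IDs that were higher in mock leaves of the mutants overlapped with those raised by infection, even between comparisons with no library in common. Of 761 IDs higher in Sldmr6-1.2-mock than in WT-mock, 309 also rose with infection in Sldmr6-1.1, where independent lists would share 86.4, and 20 of 123 lower IDs also fell (11.1 for independent lists), with 11 in opposite directions. Of 1146 IDs higher in Sldmr6-1.1-mock, 493 rose with infection in Sldmr6-1.2 (124.5 for independent lists), and 81 of 303 lower IDs fell (31.6), with 21 in opposite directions. Independent lists are a weak reference where many genes shift together between plants. No split or simulation was run for these overlaps.

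A hypothesis is that genes of the infection response may already be shifted in mock leaves of the mutants beyond the IDs called there. It was tested on the signed mean of genes called for infection in the other line and in neither line against wild type in mock leaves, relative to the mean of WT-mock leaves. Leaving out the called IDs lowers this mean. Over 3229 genes Sldmr6-1.1-mock leaves stood at 0.28 ± 0.24 against 0 ± 0.13 in WT-mock (log2 scale, SD, n = 4, 3 of 4 leaves above every WT-mock leaf, exact 2-sided permutation p = 0.143, adjusted 0.143), and WT-Xg leaves at 0.74 ± 0.20. Over 3085 genes Sldmr6-1.2-mock leaves stood at 0.24 ± 0.15 against 0 ± 0.13 (3 of 4 above, exact permutation p = 0.0857, adjusted 0.114), and WT-Xg leaves at 0.73 ± 0.19. In both lines such a shift cannot be told apart from the spread between 4 plants, where the smallest p is 0.0286.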
